A study of Homo sapiens with 34 samples.

How the data were processed

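Total RNA of PC3 cells was sequenced in 34 libraries, 17 at each of 2 times (24 h and 72 h). The labels' protocols name a column clean-up of the RNA and the KAPA RNA HyperPrep kit for the libraries. Each library came with a table of deposited read counts per gene symbol. Per the submitters' processing notes, bcl2fastq 2.19, STAR 2.4.2a, HTSeq and DESeq2 were used, with no version given for HTSeq and DESeq2. The same notes name the builds GRCh37, hg19 and mm8 without saying what each was used for, so no coordinates are given here. Whether the counting used strand is not given in the sources used here, so reads of a gene and its antisense partner cannot be told apart.

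The values used were the whole-number counts that the authors deposited, before any normalization. Each table holds 55765 gene symbols and 5 lines of reads assigned to no gene. Reads in genes ranged from 25.9 to 56.0 M (median 47.8) in 33 libraries and were 5.31 M in the 24 h 2 Gy library. In those 33 libraries, 32.2% to 44.7% of aligned reads were multi-mapped and were not counted, and 7.74% to 29.7% of the uniquely aligned reads lay in no gene. Reads without molecular identifiers are not independent molecules, so intervals and detection floors cover counting error only. A floor of 3 counts corresponds to 0.0536 counts per M (CPM) in the deepest library.

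Doses and times were taken from the sample titles. The library titled as 8 Gy at 72 h carries 4 Gy in its treatment label, and it was taken as 8 Gy. No batch is given in the labels. The sample-sheet numbers in the file names fall into 3 series, which were read as 3 sequencing runs: A (12 libraries), B (12) and C (10). This is an inference. Run A holds 24 h libraries, run C holds 72 h libraries and run B holds both. At 72 h every 0 Gy library is in run B and every 8 Gy library in run C.

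The analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with low counts were removed with filterByExpr, libraries were scaled by TMM factors (0.661 to 1.23), and edgeR's quasi-likelihood F-test was applied, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. One additive model held all 34 libraries: time, radiation dose as a 4-level factor within each time, and ONC201 dose as a 4-level factor within each time (14 coefficients, 20 residual degrees of freedom, 19478 genes). The untreated and DMSO libraries both stood at 0 Gy and 0 µM. Since each condition has 1 library, the spread is the departure from additivity, and p-values measure only the spread between these libraries, which may be technical. ONC201 was tested as the mean of its 3 doses against 0 µM, and radiation as 8 Gy against 0 Gy, at each time. Further contrasts were the ONC201 effect at 72 h minus that at 24 h, 15 against 5 µM, and 72 h against 24 h without drug or radiation. The combination was tested with 1 added term per time, irradiated at any dose by ONC201 at any dose, which is the ONC201 effect in irradiated cells minus that in unirradiated cells (16 coefficients, 18 residual degrees of freedom, 20123 genes). DMSO against untreated was tested with 1 term shared by both times.

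In all, 29 gene lists were written from general knowledge: the integrated stress response, endoplasmic reticulum chaperones, mitochondrial chaperones and proteases, mitochondrially encoded transcripts, nuclear oxidative phosphorylation genes, the tricarboxylic acid cycle, the mitochondrial ribosome, glycolysis, cholesterol biosynthesis, fatty acid synthesis, DNA replication and G1/S, G2 and mitosis, p53 targets, double-strand break repair, replication-dependent histones, the type I interferon response, NF-kB and inflammatory cytokines, death receptors and apoptosis, cytosolic ribosomal proteins, MYC targets and ribosome biogenesis, the heat shock response, the oxidative stress response, the hypoxia response, epithelial-mesenchymal transition, and markers of prostate luminal, neuroendocrine, immune, fibroblast and endothelial cells. Lists were tested with camera from limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. At the preset correlation, the test fixed first, camera passed 16 lists even for DMSO against untreated, so the report gives the p with an estimated correlation. That choice was made after the DMSO result was seen. The fry test stands beside it: its PValue tests whether a list's genes move on balance one way and its Mixed value whether they change in either direction, and neither compares the list with other genes.

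Genes were named by a rule. For ONC201 and for radiation at each time, the rule took the 10 largest changes each way among genes with adjusted p under 0.05, a mean log2 CPM of at least 3 and the same sign in all 4 strata of the other factor. For the other contrasts it took 5 each way without the strata condition. Symbols of unnamed clones were passed over. Besides these came 26 genes chosen for ONC201 and radiation whatever their result, and up to 4 members of each list. The design, the lists, the rule and the alternatives not described as added later were fixed before the data were examined.

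The pipeline was tested on simulated data drawn from the real means and library sizes, with 200 genes changed in each of 3 simulations. Each gene had 1 mean over all libraries, and genes were drawn independently without effects of time or run. The false calls therefore do not cover a run that coincides with dose or genes that vary together. For ONC201 at 24 h, with 18800 genes tested, edgeR recovered 40 of 67 genes changed 1.5-fold, 58 of 67 changed 2-fold and 66 of 66 changed 4-fold, and called 8 of 18547 unchanged genes. For radiation at 72 h, with 18816 genes tested, it recovered 11 of 67, 49 of 67 and 66 of 66, and called 5 of 18563 unchanged genes. For the combination at 72 h, with 19119 genes tested, it recovered 2 of 67, 18 of 67 and 61 of 66, and called 3 of 18866. By camera at the preset correlation, a raised stress-response list ranked 1 in each simulation, while 3, 1 and 0 other lists were called as well, for ONC201, radiation and the combination. The estimated correlation was not tried on simulated data.

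The alternatives were DESeq2, RLE size factors, 2 other filters on low counts, the inferred run or the share of reads outside genes as a covariate, the libraries of 1 time, 1 run or 1 arm, linear dose terms, the other dose label of the 72 h 8 Gy library, offsets for GC content and gene length, a model with the combination term for time, and each library left out in turn. GC content and length were taken by symbol from the GENCODE annotation, whose build differs from that of the counts. Genes without reads and the genes removed by the filter were not tested.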

Results

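Gene expression was measured by RNA sequencing in PC3 cells, a human prostate cancer line without functional p53, after ONC201 and radiation. ONC201 is a small molecule that activates the mitochondrial protease ClpP. The series sets out to evaluate it as a radiosensitizer and asks how radiation alters the response to it. At 24 h and at 72 h, 4 radiation doses (0, 2, 4 and 8 Gy) were crossed with 4 ONC201 doses (0, 5, 10 and 15 µM), with 1 library per condition. An untreated and a 0.1% DMSO library both stood at 0 Gy and 0 µM, which made 17 libraries per time and 34 in all. No condition had a replicate culture, so the error of each comparison is the spread of libraries around an additive model of the doses. Depth was 25.9 to 56.0 M reads in genes in 33 libraries. Where a gene is named as having the largest change of a comparison, this is among genes with a mean log2 CPM of at least 3, since larger values occur in genes with few reads.

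The 24 h 2 Gy library stood apart, with 5.31 M reads in genes and 16260 genes with a read, against 21378 to 26826 genes in the others. Multi-mapped reads made up 90.5% of its aligned reads (95% Wilson interval 90.5 to 90.5), and the highest value of the other 33 libraries was 44.7%. The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 took 37.6% of its gene reads (95% Wilson interval 37.6 to 37.7), and at most 0.0557% elsewhere. It remained in every fit unless stated. No pair of libraries was identical.

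At 24 h, the 12 libraries with ONC201 were compared with the 5 without it over all radiation doses. Genes of the integrated stress response, which the transcription factors ATF4 and CHOP drive, were higher with the drug. Of 53 genes 48 rose and 2 fell (48 and 3 adjusted over the list alone). Their median log2 fold change was 1.47 (camera adjusted p = 1.37e-07 with an estimated correlation). CHAC1, which degrades glutathione, stood at 91.9 ± 9.07 CPM (SD, n = 12) with ONC201 and 7.65 ± 2.38 CPM (n = 5) without it. This is a log2 fold change of 3.53 ± 0.34 (SE, adjusted p = 8.95e-09). The pseudokinase TRIB3 stood at 389 ± 38.5 against 50.4 ± 10.2 CPM, and the mTORC1 inhibitor DDIT4 at 261 ± 29 against 21.4 ± 1.83 CPM. DDIT4 (3.56 ± 0.25), SESN2 (3.27 ± 0.29), TRIB3 (2.93 ± 0.16) and asparagine synthetase ASNS (2.90 ± 0.14) rose. The secreted factor GDF15 (2.56 ± 0.40), CHOP itself (DDIT3, 2.13 ± 0.27), ATF3 (1.47 ± 0.26) and ATF4 (1.45 ± 0.17) rose as well. The adjusted p of these genes lay between 2.37e-15 (ASNS) and 0.000144 (ATF3). The hormone gene FGF21 (4.99 ± 0.57), INHBE (4.60 ± 0.44) and the NKG2D ligand ULBP1 (3.61 ± 0.31) had the largest changes of this list at any level of expression, although FGF21 stood at only 0.0201 CPM without the drug. Other genes with the largest rises were KRT16 (4.20 ± 0.34), a keratin with near-identical pseudogenes, ADM2 (3.87 ± 0.36), PAPPA2 (3.82 ± 0.21), PCK2 (3.14 ± 0.14), S100P (3.14 ± 0.36) and NUPR1 (3.03 ± 0.27), each higher at all 4 radiation doses.

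The unfolded protein response of the endoplasmic reticulum is read from its chaperones and the targets of ATF6 and XBP1. Of 34 such genes 9 rose and 2 fell (11 and 2 adjusted over the list alone), with adjusted p = 0.546 with an estimated correlation. Those that rose included the sensor kinase ERN1 (1.88 ± 0.24), DNAJB9 (1.44 ± 0.30), the transcription factor XBP1 (1.42 ± 0.13) and the chaperone BiP (HSPA5, 1.17 ± 0.23). The death receptor gene TNFRSF10B, which encodes DR5, rose by a log2 fold change of 0.67 ± 0.12 (adjusted p = 0.000126). In all 8 of 31 death receptor and apoptosis genes rose while 2 fell (8 and 3 adjusted over the list alone, adjusted p = 0.52 with an estimated correlation). Among 25 p53 targets, 9 rose and 2 fell (9 and 3 adjusted over the list alone, adjusted p = 0.0544 with an estimated correlation). The cell cycle inhibitor CDKN1A (1.31 ± 0.16) and the apoptosis gene BBC3 (2.58 ± 0.37) were among those that rose, and MDM2 stood at -0.19 ± 0.10 (adjusted p = 0.236). The cystine transporter SLC7A11 (2.06 ± 0.19) and HMOX1 (1.46 ± 0.17) were among 7 of 24 NRF2 targets that rose (9 adjusted over the list alone, adjusted p = 0.137 with an estimated correlation). The cytokines CXCL3 (1.97 ± 0.30), CXCL2 (1.81 ± 0.27) and IL1B (1.43 ± 0.21) were among 7 of 22 NF-kB genes that rose (8 adjusted over the list alone, adjusted p = 0.123 with an estimated correlation).

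Mitochondrially encoded transcripts were lower with ONC201 at 24 h. In this list 11 of 13 fell (12 adjusted over the list alone), with a median log2 fold change of -1.27 (adjusted p = 0.092 with an estimated correlation, and 0.00032 for a shift on balance one way by fry). MT-ND6 fell by 2.42 ± 0.20 on the log2 scale and MT-CO1 by 1.62 ± 0.21, from 11052 ± 2121 CPM without the drug to 3578 ± 461 CPM with it. MT-ND4L (-1.50 ± 0.29) and MT-CO2 (-1.42 ± 0.24) fell too, although near-identical nuclear copies leave reads of such genes uncertain. Without the 24 h 2 Gy library, whose mitochondrial ribosomal share is given with the depth, 8 of the 13 fell, with a median of -0.99. The nuclear genes of oxidative phosphorylation moved little, with 5 of 56 lower (5 adjusted over the list alone, adjusted p = 0.804 with an estimated correlation). Of the mitochondrial chaperones and proteases, 1 of 18 rose and 4 fell (1 and 4 adjusted over the list alone, adjusted p = 0.546 with an estimated correlation): the protease LONP1 rose by 0.56 ± 0.12 and the chaperonin subunit HSPE1 fell by 0.91 ± 0.19. The drug target CLPP (-0.13 ± 0.13, adjusted p = 0.558) and its partner CLPX (-0.05 ± 0.09, adjusted p = 0.796) did not pass.

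Genes of DNA replication and the G1/S transition fell in 36 of 38 cases at 24 h (36 adjusted over the list alone), with a median of -0.96 (adjusted p = 0.035 with an estimated correlation). The replication factor MCM10 (-1.52 ± 0.22), E2F2 (-1.53 ± 0.31) and cyclin E2 (CCNE2, -1.46 ± 0.24) were among them. Outside that list ORC1 (-1.78 ± 0.18), ZNF367 (-1.57 ± 0.15), CDC25A (-1.45 ± 0.17) and the chromatin remodeller HELLS (-1.42 ± 0.19) fell as well. Of 49 genes of G2 and mitosis, 16 fell (20 adjusted over the list alone, adjusted p = 0.506 with an estimated correlation), and CCNB1 stood at -0.35 ± 0.26 (adjusted p = 0.414). Hypoxia genes split. Carbonic anhydrase CA9 (-2.79 ± 0.34) and BNIP3 (-0.99 ± 0.11) were among 11 of 20 that fell, and VEGFA (1.88 ± 0.18) was one of 2 that rose (11 and 2 adjusted over the list alone, adjusted p = 0.0103 with an estimated correlation). Lactate dehydrogenase LDHA (-0.90 ± 0.12) and PDK1 (-0.98 ± 0.12) were among 13 of 21 glycolysis genes that fell (15 adjusted over the list alone, adjusted p = 0.137 with an estimated correlation). Heat shock genes fell in 8 of 14 cases (8 adjusted over the list alone, adjusted p = 0.17 with an estimated correlation), and mitochondrial ribosome genes in 5 of 36 (4 adjusted over the list alone, adjusted p = 0.554 with an estimated correlation). The glutamate transporter SLC1A3 (-1.73 ± 0.14) and the bombesin receptor GRPR (-1.69 ± 0.17) also fell at all 4 radiation doses.

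In total, edgeR called 3496 of 19478 genes for ONC201 at 24 h, 1752 higher and 1744 lower, and 827 of them changed at least 2-fold. Without the 24 h 2 Gy library 2421 passed, the lowest count with any single library left out. A model of the 24 h libraries alone called 5461. Within inferred run A alone 4323 genes passed, 2255 higher and 2068 lower, and with the run as a covariate 1988. In the unirradiated libraries alone, 3 with ONC201 and 2 without, 5 genes passed. The doses gave similar numbers: 1720 genes at 5 µM, 1665 at 10 µM and 2392 at 15 µM.

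**Figure D1:**
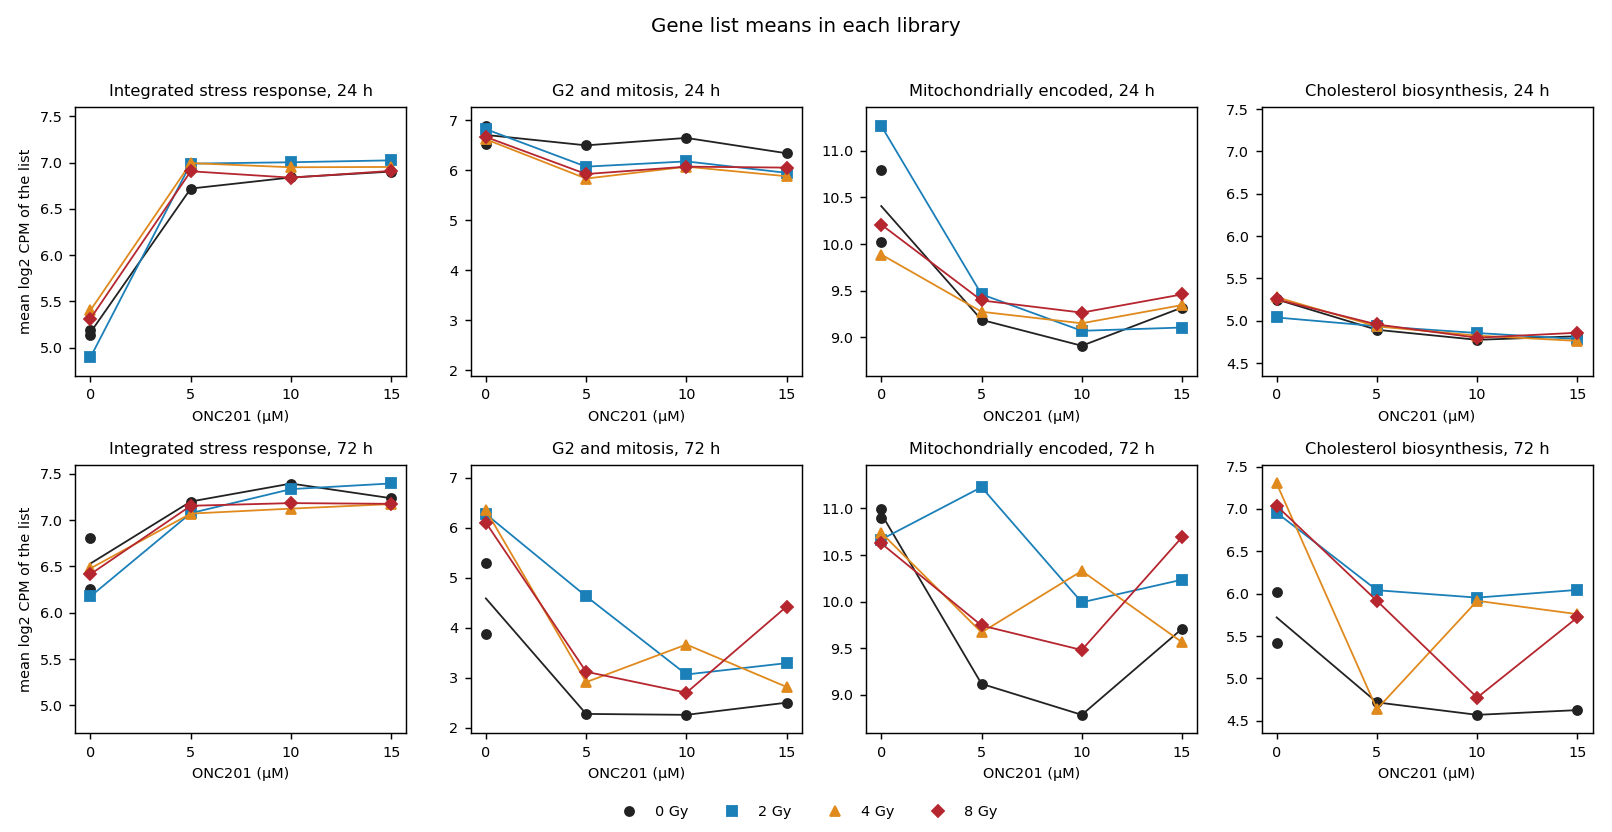
Mean log2 CPM of the gene lists drawn in each panel, at 24 h (upper panels) and 72 h (lower panels), against the ONC201 dose in µM. Points are single libraries, lines join the means per radiation dose, and at 24 h the integrated stress response list, of which 48 of 53 genes rose, lies higher at each ONC201 dose than at 0 µM.

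**Figure D2:**
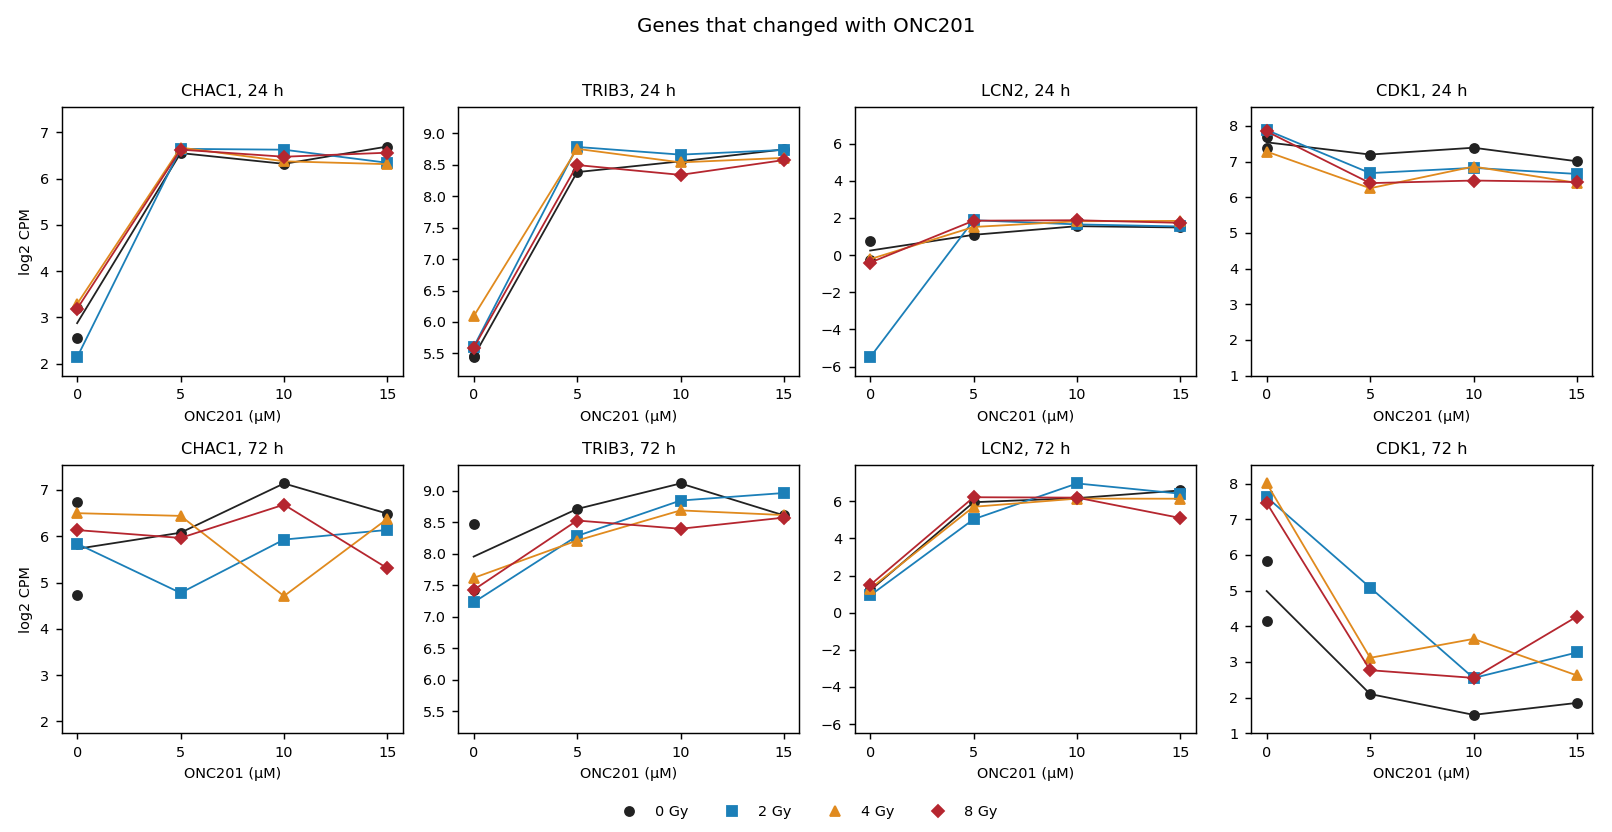
Log2 CPM of CHAC1, TRIB3, LCN2 and CDK1 at 24 h (upper panels) and 72 h (lower panels) against the ONC201 dose in µM. Points are single libraries and lines join the means per radiation dose: CHAC1 differed by a log2 fold change of 3.53 with the drug at 24 h and of 0.04 at 72 h, and LCN2 by 4.90 at 72 h.

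At 72 h the same comparison asked which changes ONC201 maintains. The mitotic programme was far lower with the drug. Of 49 genes of G2 and mitosis 48 fell (49 adjusted over the list alone), with a median log2 fold change of -2.68 (adjusted p = 0.0305 with an estimated correlation). The mitotic kinase CDK1 stood at 9.93 ± 8.80 CPM (SD, n = 12) with ONC201 and 141 ± 99.9 CPM (n = 5) without it (log2 fold change -3.96 ± 0.28 SE, adjusted p = 4.13e-12). The mitotic genes AURKB (-3.51 ± 0.24), cyclin A2 (CCNA2, -3.41 ± 0.24), topoisomerase TOP2A (-3.38 ± 0.32), the proliferation marker MKI67 (-2.96 ± 0.26) and CCNB1 (-2.52 ± 0.25) fell as well, and so did the helicase ERCC6L (-3.72 ± 0.22), which is not in the list. Replication-dependent histone genes, which are transcribed in S phase, held the largest drops, HIST1H3B (-5.09 ± 0.23) and HIST1H3C (-4.97 ± 0.23). Of the 20 listed 14 fell while 2 rose (14 and 2 adjusted over the list alone, adjusted p = 0.163 with an estimated correlation). Reads of single histone genes are uncertain because the family holds near-identical copies. In DNA replication and G1/S 34 of 38 genes fell (35 adjusted over the list alone, adjusted p = 0.0796 with an estimated correlation), with RRM2 at -2.63 ± 0.21. Of the double-strand break repair genes 23 of 33 fell and 3 rose (24 and 4 adjusted over the list alone, adjusted p = 0.132 with an estimated correlation), with RAD54L at -2.37 ± 0.23 and FANCD2 at -2.29 ± 0.20 among those that fell. CDKN1A rose by a log2 fold change of 1.88 ± 0.17 (adjusted p = 3.37e-10).

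Sterol and fatty acid synthesis were lower at 72 h. Of 23 cholesterol biosynthesis genes 22 fell (22 adjusted over the list alone), with a median of -1.36 (adjusted p = 0.0506 with an estimated correlation). The synthase HMGCS1 (-2.29 ± 0.26) was among them. Fatty acid synthase FASN (-2.54 ± 0.22) was one of 9 of 11 fatty acid synthesis genes that fell, and 1 rose (9 and 1 adjusted over the list alone, adjusted p = 0.0506 with an estimated correlation). The mitochondrially encoded transcripts were again lower in 10 of 13 cases (10 adjusted over the list alone, median -0.93, adjusted p = 0.386 with an estimated correlation), with MT-CO1 at -1.41 ± 0.22. Of the nuclear oxidative phosphorylation genes 25 of 56 fell (29 adjusted over the list alone, adjusted p = 0.683 with an estimated correlation), with SDHA at -1.13 ± 0.12, and 11 of 18 tricarboxylic acid cycle genes fell (13 adjusted over the list alone, adjusted p = 0.325 with an estimated correlation). CLPX stood at -0.31 ± 0.09 (adjusted p = 0.00814), a difference that did not pass without the 72 h 8 Gy library (adjusted p = 0.0539), and CLPP at 0.05 ± 0.13 (adjusted p = 0.806). The CLPX difference also fell short with the run as a covariate (-0.32, adjusted p = 0.0777) and without a filter on low counts (-0.31, adjusted p = 0.0932). In the unirradiated libraries alone it was -0.20 (adjusted p = 0.642).

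The largest rises at 72 h were in LCN2 (4.90 ± 0.29), which encodes the iron-siderophore carrier lipocalin, in PAPPA2 (4.27 ± 0.20), in the lysosomal LAMP3 (4.08 ± 0.29), in STK32A (3.88 ± 0.26) and in the receptor subunit IL20RB (3.73 ± 0.25). LCN2 stood at 70.3 ± 25.1 CPM (SD, n = 12) with ONC201 and 2.33 ± 0.34 CPM (n = 5) without it. FER1L6 (3.41 ± 0.26), SLITRK6 (3.30 ± 0.34), GPR1 (3.12 ± 0.28), S100P (3.04 ± 0.34) and the pseudogene RPLP0P2 (3.56 ± 0.32), whose reads can come from RPLP0, followed. The integrated stress response list was still higher, with 43 of 53 genes up (44 adjusted over the list alone), a median of 0.66 and adjusted p = 0.0276 with an estimated correlation. INHBE (3.13 ± 0.34), FGF21 (2.75 ± 0.34), CCPG1 (2.30 ± 0.22), ASNS (1.36 ± 0.12), TRIB3 (1.01 ± 0.15), DDIT3 (0.93 ± 0.25) and ATF4 (0.62 ± 0.17) rose, while CHAC1 stood at 0.04 ± 0.27 (adjusted p = 0.928). GDF15 (1.44 ± 0.41, adjusted p = 0.00666) and XBP1 (0.42 ± 0.12, adjusted p = 0.00733) did not pass without the 72 h 2 Gy library (adjusted p = 0.0595 and 0.0736). With the inferred run as a covariate ATF4 (0.55, adjusted p = 0.0889) and DDIT3 (0.87, adjusted p = 0.0683) did not pass. Neither did XBP1 (0.45, adjusted p = 0.054) or GDF15 (0.56, adjusted p = 0.414). Of the endoplasmic reticulum chaperones and targets 15 of 34 rose and 2 fell (16 and 2 adjusted over the list alone, adjusted p = 0.525 with an estimated correlation), with HSPA5 at 1.06 ± 0.23, SEL1L at 1.20 ± 0.15 and ERN1 at 1.43 ± 0.23. TNFRSF10B rose by 0.84 ± 0.12 (adjusted p = 1.33e-06). Type I interferon genes moved both ways, with 13 of 33 higher, RSAD2 (2.20 ± 0.33) among them, and 6 lower, OAS1 (-1.26 ± 0.25) among them (14 and 6 adjusted over the list alone, adjusted p = 0.71 with an estimated correlation).

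For ONC201 at 72 h edgeR called 6807 of 19478 genes, 3152 higher and 3655 lower, and 2498 changed at least 2-fold. Within inferred run B, where the drug was given without radiation, 1371 genes passed, 367 higher and 1004 lower, of which 1299 were also in the 6807 with the same sign, and 3975 passed with the run as a covariate. Each dose in run B at 72 h has 1 library and its own term, so the error of that fit rests on the DMSO and untreated libraries alone. In run B alone ATF4 (0.47, adjusted p = 0.403), DDIT3 (0.84, adjusted p = 0.235), TRIB3 (0.73, adjusted p = 0.203), XBP1 (0.58, adjusted p = 0.261) and HSPA5 (1.04, adjusted p = 0.0622) did not pass, and GDF15 stood at -0.20 (adjusted p = 0.831).

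How the ONC201 response differed between the times was tested directly as the effect at 72 h minus that at 24 h. The drug effect on the stress response became smaller. Without drug or radiation most genes of this list were higher at 72 h than at 24 h, so the smaller effect stands against a raised baseline. In that baseline time and run cannot be told apart. Of 53 integrated stress response genes 28 had a lower effect at 72 h and 3 a higher one (42 and 4 adjusted over the list alone), with a median difference of -0.77 (adjusted p = 0.00502 with an estimated correlation). CHAC1 differed by -3.49 ± 0.40 (SE, adjusted p = 1.24e-06), ADM2, which is not in the list, by -3.13 ± 0.42, JDP2 by -2.90 ± 0.28, SESN2 by -2.54 ± 0.34, TRIB3 by -1.92 ± 0.20 and ASNS by -1.53 ± 0.17. Without ONC201, CHAC1 stood at 7.65 ± 2.38 CPM at 24 h and 70.1 ± 30.8 CPM at 72 h (SD, n = 5 each), and with the drug at 91.9 ± 9.07 and 71.4 ± 32.7 CPM (n = 12 each). The mitotic response became larger, with 48 of 49 genes lower in the difference (48 adjusted over the list alone, median -2.12, adjusted p = 0.0353 with an estimated correlation). CDC25C (-3.35 ± 0.42) and CDK1 (-3.09 ± 0.42) were among them, and the histone gene HIST1H3B differed by -4.64 ± 0.36. Of the cholesterol genes 12 of 23 differed downward (16 adjusted over the list alone, adjusted p = 0.124 with an estimated correlation), and 9 of 22 NF-kB genes did (10 adjusted over the list alone, with 1 upward, adjusted p = 0.0926 with an estimated correlation), IL8 (-2.30 ± 0.38) and IL1B (-1.83 ± 0.28) among them. Hypoxia genes differed upward in 9 of 20 cases and downward in 1 (11 and 2 adjusted over the list alone, adjusted p = 0.00502 with an estimated correlation), with P4HA1 at 1.29 ± 0.17 and BNIP3 at 1.16 ± 0.16. LCN2 (3.20 ± 0.37), LAMP3 (2.67 ± 0.38), IL1RL1 (2.37 ± 0.36), SLITRK6 (2.31 ± 0.44) and PCDH7 (2.16 ± 0.26) had the largest upward differences. In all 1926 genes differed, 712 upward and 1214 downward, and 695 with the run as a covariate. Of the genes higher at 24 h, 1052 were also higher at 72 h, where independent lists would share 284, and of those lower 1080 were also lower, where independent lists would share 327. Another 36 and 18 had the opposite sign at 72 h.

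No gene was called between 15 and 5 µM ONC201 at 24 h or at 72 h. edgeR and DESeq2 both gave 0 genes at each time, and 142 genes at 24 h and 831 at 72 h had an unadjusted p under 0.05 in edgeR. CHAC1 stood at -0.14 ± 0.35 and ASNS at 0.13 ± 0.15 at 24 h. At 72 h ASNS stood at 0.25 ± 0.15 (adjusted p = 0.913). In the integrated stress response list 0 of 53 genes passed at either time, adjusted over the list alone too (adjusted p = 0.855 at 24 h and 0.566 at 72 h with an estimated correlation).

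The radiation comparison at 24 h set the 4 libraries at 8 Gy against the 5 at 0 Gy, over all ONC201 doses, so it averages over cells with and without the drug. The TGF-beta pathway regulator PMEPA1 fell the most, from 59.2 ± 10.4 CPM (SD, n = 5) at 0 Gy to 16.4 ± 0.572 CPM (n = 4) at 8 Gy (log2 fold change -1.87 ± 0.21 SE, adjusted p = 1.84e-05). HELLS (-1.29 ± 0.26), NEDD9 (-1.06 ± 0.24) and the matrix genes THBS1 (-0.92 ± 0.18) and CTGF (-0.80 ± 0.15) also fell. So did the apoptosis gene BCL2L11 (-0.83 ± 0.19), RUNX1 (-0.82 ± 0.17), SRSF6 (-0.78 ± 0.18), FBXO11 (-0.66 ± 0.15) and the mitochondrial tRNA MT-TT (-1.16 ± 0.23), and ANGPTL4 (-1.15 ± 0.25) as well. IL1B rose from 23.1 ± 11.7 to 66.1 ± 20.4 CPM (1.42 ± 0.24, adjusted p = 0.0064), and IL1A by 1.53 ± 0.31. In the NF-kB list these were the 2 of 22 genes that rose (2, with 1 lower, adjusted over the list alone, adjusted p = 0.815 with an estimated correlation). IFIT2, an interferon-induced gene, rose by 0.98 ± 0.16 as the 1 gene of 33 in its list that passed (4 adjusted over the list alone, adjusted p = 0.74 with an estimated correlation). The RNase component RMRP (1.49 ± 0.33), IGFBP6 (1.15 ± 0.23), IFI27L2 (1.04 ± 0.23), ARHGAP24 (0.88 ± 0.15), RPP25L (0.87 ± 0.20), JOSD2 (0.86 ± 0.19) and PHF23 (0.86 ± 0.14) rose as well. RMRP is one of the short noncoding RNAs that together took 3.29% to 5.24% of gene reads in the 0 Gy libraries and 7.10% to 14.4% in the 8 Gy libraries of 24 h, so its rise may belong to a difference in library composition. No p53 target passed among 25 (edgeR, 1 adjusted over the list alone), and CDKN1A stood at -0.23 ± 0.19, MDM2 at -0.11 ± 0.13 and PHLDA3 at 0.67 ± 0.18 (adjusted p = 0.0785). The integrated stress response list had 0 of 53 genes past the threshold (0 adjusted over the list alone, adjusted p = 0.983 with an estimated correlation), with ATF4 at 0.14 ± 0.20 and TRIB3 at -0.01 ± 0.17. Cytosolic ribosomal protein genes had 0 of 55 past the threshold, 26 of them higher adjusted over the list alone (median 0.56, adjusted p = 0.74 with an estimated correlation).

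For radiation at 24 h edgeR called 73 of 19478 genes, 50 higher and 23 lower (20 at 2 Gy and 22 at 4 Gy), while 2891 had an unadjusted p under 0.05 and DESeq2 called 546. A model of the 24 h libraries alone called 1842, 1111 higher and 731 lower, 71 of the 73 among them. Run and dose partly coincide, since the 8 Gy libraries with ONC201 lie in run B and the 0 Gy libraries in run A: with the run as a covariate 0 genes passed in edgeR (958 at an unadjusted p under 0.05). Run A holds 1 library at 8 Gy, so the 656 genes that passed within it rest on that library, assumed to vary as the others do, and cannot settle the question. Single libraries moved the count for radiation at 24 h by more than 1.5 times. Among 24 h libraries, it was 2 without ONC201 at 5 µM, 4 without 15 µM and 8 without 10 µM. Without the 8 Gy libraries it was 6 (5 µM), 13 (10 µM), 9 (15 µM) and 373 (no ONC201). Without those at 2 Gy it was 41 (10 µM) and 39 (15 µM), and without those at 4 Gy it was 43 (no ONC201), 43 (5 µM) and 43 (15 µM). The DMSO library gave 44 when left out and the untreated one 48. Among 72 h libraries the count was 45 without 8 Gy, 46 without 2 Gy with 15 µM, 158 without 8 Gy with 10 µM, 172 without the untreated one, 262 without 4 Gy with 10 µM and 270 without 4 Gy with 5 µM.

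At 72 h cytokine and inflammatory genes rose with radiation. In the NF-kB list 14 of 22 were higher (14, with 1 lower, adjusted over the list alone), with a median log2 fold change of 1.29 (adjusted p = 0.0121 with an estimated correlation). The matrix protease MMP3 (2.85 ± 0.36, from 0.191 ± 0.0563 to 1.36 ± 0.246 CPM), CSF2 (2.41 ± 0.43), IL1A (2.37 ± 0.29) and IL8 (2.34 ± 0.34) were among them, and the cytokine IL11 (2.07 ± 0.27) rose too. Type I interferon genes rose in 17 of 33 cases (20 adjusted over the list alone, median 0.82, adjusted p = 0.0398 with an estimated correlation), with RSAD2 at 1.96 ± 0.37, IFI44 at 1.85 ± 0.26 and OASL at 1.65 ± 0.30. Sterol genes rose as well. Of 23 cholesterol biosynthesis genes 17 were higher and 1 lower (20 and 1 adjusted over the list alone, median 0.93, adjusted p = 0.153 with an estimated correlation, and 0.0017 by fry for a shift on balance one way). The sterol sensor INSIG1 went from 31.7 ± 21.9 CPM (SD, n = 5) at 0 Gy to 188 ± 125 CPM (n = 4) at 8 Gy (2.79 ± 0.47 SE, adjusted p = 0.000487), and HMGCS1 (2.51 ± 0.35) and MSMO1 (2.08 ± 0.36) rose with it. Of 49 genes of G2 and mitosis 43 rose (46 adjusted over the list alone, median 1.34, adjusted p = 0.215 with an estimated correlation, and 0.00554 by fry). TTK (2.06 ± 0.33), CDK1 (1.83 ± 0.38) and DLGAP5 (1.80 ± 0.38) were among them. Without drug or radiation most genes of this list were lower at 72 h than at 24 h, so the rises stand against a lowered baseline. In the model with the combination term MKI67 differed by -2.07 and CCNB1 by -1.81 between those controls, among which time and run cannot be told apart. The dehydrogenase DHRS9 (2.93 ± 0.25), FGFBP1 (2.81 ± 0.40), the phosphatase DUSP1 (2.67 ± 0.52), the peptide hormone ADM (2.16 ± 0.31) and the kinase SGK1 (2.10 ± 0.33) were the other largest rises, each higher at all 4 ONC201 doses.

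Ribosome biogenesis and MYC target genes were lower at 72 h, with 17 of 28 down and 1 up (18 and 1 adjusted over the list alone, median -0.51, adjusted p = 0.0548 with an estimated correlation). The RNA polymerase I subunit POLR1A (-1.09 ± 0.22) and RRS1 (-0.94 ± 0.19) fell among them. In the integrated stress response list 10 of 53 fell and 2 rose (12 and 4 adjusted over the list alone, adjusted p = 0.544 with an estimated correlation). SLC6A9 (-1.22 ± 0.26), CBS (-0.97 ± 0.18) and SLC7A11 (-0.89 ± 0.22) were among those that fell. The largest drops were in SSTR5-AS1 (-2.03 ± 0.34) and SSTR5 (-1.83 ± 0.40), an antisense pair that counting may not separate. NCOA5 (-1.51 ± 0.37), ZNF469 (-1.50 ± 0.40), the morphogen SHH (-1.50 ± 0.47), B3GALT6 (-1.48 ± 0.26), ZBED3 (-1.48 ± 0.34), TIGD5 (-1.45 ± 0.40), FJX1 (-1.42 ± 0.30) and the mucin MUC5B (-1.42 ± 0.36) followed. Epithelial-mesenchymal transition genes rose in 9 of 23 cases and fell in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.287 with an estimated correlation), with SNAI1 at 1.46 ± 0.24. Among p53 targets 4 of 25 rose and 2 fell (10 and 3 adjusted over the list alone, adjusted p = 0.233 with an estimated correlation). PLK2 rose by 1.67 ± 0.21, and CDKN1A stood at 0.47 ± 0.19 (adjusted p = 0.0856) and MDM2 at -0.01 ± 0.13. In the death receptor and apoptosis list 7 of 31 rose and 2 fell (9 and 3 adjusted over the list alone, adjusted p = 0.322 with an estimated correlation), with PMAIP1 at 1.16 ± 0.20. Of 33 double-strand break repair genes 3 rose and 1 fell (6 and 2 adjusted over the list alone, adjusted p = 0.877 with an estimated correlation).

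**Figure D3:**
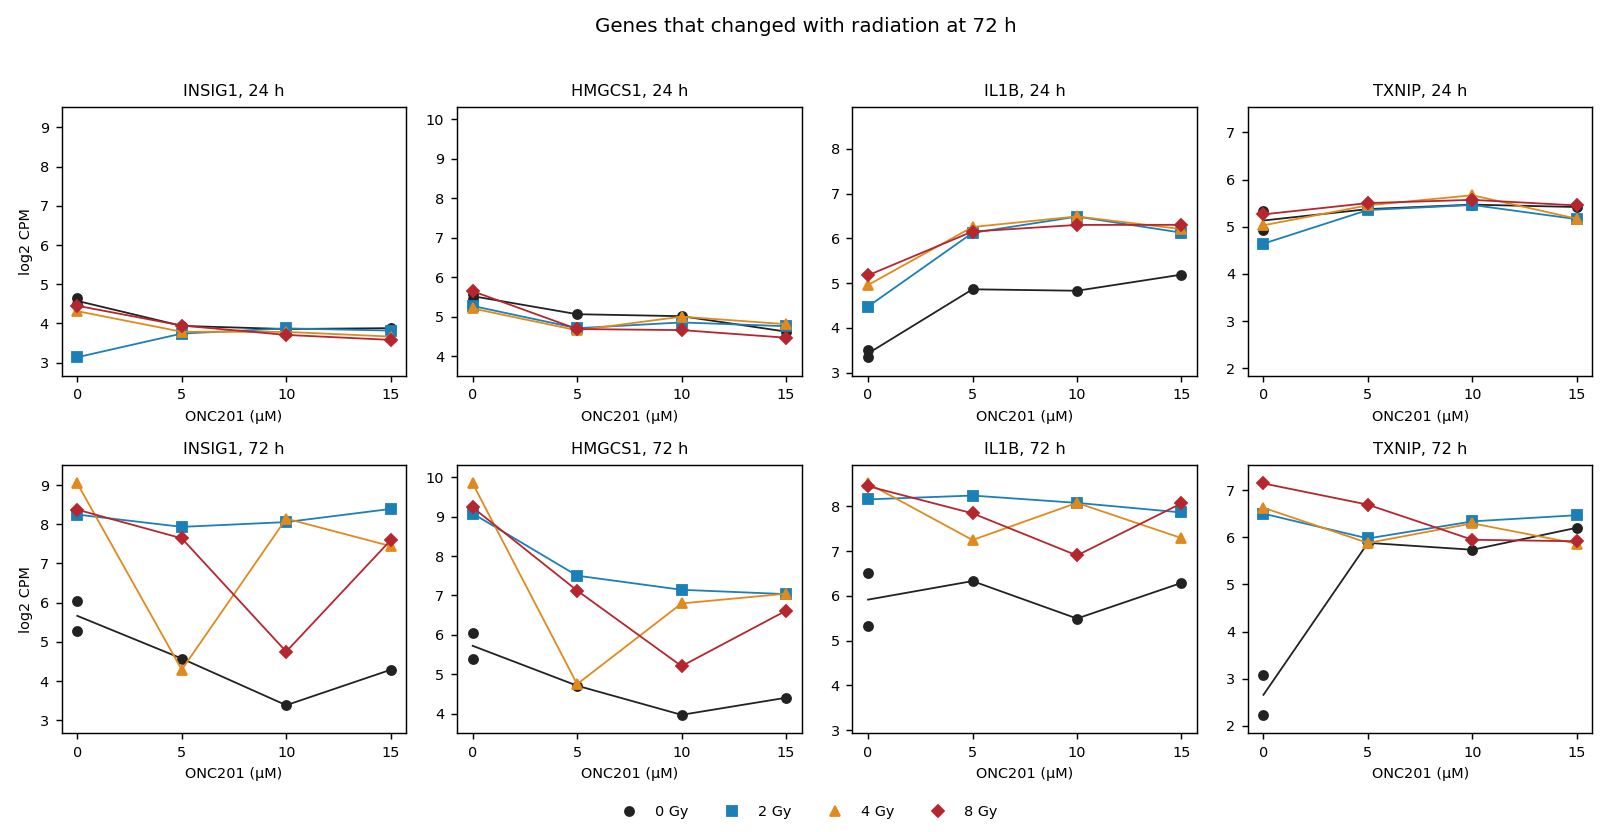
Log2 CPM of INSIG1, HMGCS1, IL1B and TXNIP at 24 h (upper panels) and 72 h (lower panels) against the ONC201 dose in µM. Points are single libraries and lines join the means per radiation dose: at 72 h INSIG1 was higher at 8 Gy than at 0 Gy by a log2 fold change of 2.79 and HMGCS1 by 2.51, and TXNIP was lowest in the 2 libraries without drug or radiation.

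For radiation at 72 h edgeR called 2719 of 19478 genes, 1425 higher and 1294 lower, 953 of them at least 2-fold, with 6314 genes at 2 Gy and 2327 at 4 Gy. A model of the 72 h libraries alone called 675, fewer than the 1842 of the 24 h libraries alone, so which time has the larger response depends on the model. The difference of the 8 Gy effects, 72 h minus 24 h, had 467 genes, 298 upward and 169 downward. At this time every 0 Gy library lies in inferred run B and every 8 Gy library in run C. Within run B, 2 and 4 Gy without ONC201 against 0 Gy gave 392 genes, 142 higher and 250 lower, 306 of them among the 2719 with the same sign, and 104 genes passed with the run as a covariate. The treatment label of the 72 h 8 Gy library conflicts with its title, and 1295 genes passed with it taken as 4 Gy. Left out singly, the libraries that moved the count of radiation at 72 h by more than 1.5 times were those of 8 Gy (960), 8 Gy with 5 µM (1186), 8 Gy with 15 µM (1681) and 0 Gy with 10 µM (1537). The libraries of 4 Gy with 5 µM and 8 Gy with 10 µM lay near the unirradiated ones, and 4237 genes passed without them, in a fit added after the data were examined. Short noncoding RNAs (RN7SL1, RN7SL2, RN7SK, RPPH1 and RMRP) took 3.29% to 26.9% of gene reads over all libraries. At 72 h their share was 8.62% to 18.8% without radiation, highest with 15 µM, and 18.1% to 21.3% in the libraries of 2 and 4 Gy alone. It was 22.8% to 26.9% in the libraries of 2 Gy with 5, 10 and 15 µM and 4 Gy with 10 µM, and 11.4% to 14.8% in those of 4 Gy with 5 and 15 µM. The 4 libraries of 8 Gy, at 9.79% to 15.5%, lay inside the range without radiation.

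Whether radiation altered the response to ONC201 was tested as the ONC201 effect in irradiated cells minus that in unirradiated cells. At 72 h TXNIP, a glucose-responsive inhibitor of thioredoxin and glucose uptake, had the largest negative difference in this comparison (-3.82 ± 0.33 SE, adjusted p = 7.5e-08). TXNIP stood at 8.45 CPM in the DMSO and 4.69 CPM in the untreated library at 72 h and at 53.3 to 141 CPM in the other 72 h libraries, so its difference rests on those 2 libraries. GDF15 differed upward by 2.61 ± 0.50 (adjusted p = 0.00938). It stood at 507 and 1193 CPM in the DMSO and untreated libraries, at 672 to 908 CPM with ONC201 alone, at 179 to 312 CPM with radiation alone and at 668 to 2653 CPM with both. HES1 differed by 2.97 ± 0.55, with 300 CPM in the untreated and 43.9 CPM in the DMSO library. CP (2.89 ± 0.62), FAM135B (3.30 ± 0.81) and TTN (2.99 ± 0.63) differed upward, and PTX3 (-1.86 ± 0.33), TSC22D3 (-1.74 ± 0.30), HOXA3 (-1.67 ± 0.40) and SNORD3B-2 (-2.45 ± 0.54) downward. In the NF-kB list 2 of 22 differed downward, CXCL3 (-2.03 ± 0.38) and TNFAIP3 (-1.26 ± 0.25), and 2 adjusted over the list alone (adjusted p = 0.446 with an estimated correlation). In the interferon list 2 of 33 differed upward, OAS1 (2.10 ± 0.31) and IFIT3 (1.35 ± 0.27), and 2 adjusted over the list alone (adjusted p = 0.804 with an estimated correlation). Of the mitochondrially encoded transcripts 1 of 13 passed, MT-CYB (1.89 ± 0.40), and 7 adjusted over the list alone (adjusted p = 0.446 with an estimated correlation). The integrated stress response list had 2 of 53 upward (3, with 2 downward, adjusted over the list alone, adjusted p = 0.867 with an estimated correlation), with CHKA at 1.23 ± 0.25. CHAC1 (-0.76 ± 0.57), TRIB3 (0.36 ± 0.29), ATF4 (0.18 ± 0.34), DDIT3 (0.06 ± 0.51) and HSPA5 (-0.10 ± 0.47) did not pass.

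For the combination at 72 h edgeR called 160 of 20123 genes, 118 upward and 42 downward, and DESeq2 called 447. No within-run value can be had, because every culture with both treatments lies in run C and every unirradiated one in run B, and 1 gene passed with the run as a covariate, as in a model of the 72 h libraries alone. Left out singly, 8 libraries of 72 h moved the count of the combination at 72 h by more than 1.5 times: untreated (28), DMSO (575), ONC201 at 5 µM (70) and 15 µM (44), 2 Gy (97), 4 Gy (44), 8 Gy (82) and 4 Gy with 5 µM (252). At 24 h, edgeR called 85 genes for the combination within run A, 28 upward and 57 downward. Run A holds no library of 8 Gy with ONC201, so these come from 2 and 4 Gy. They draw in part on the 24 h 2 Gy library, which stood apart with 5.31 M reads in genes. In the fit of all libraries edgeR called 0 genes for the combination at 24 h (1008 at an unadjusted p under 0.05, and 7 in DESeq2). GDF15 stood at 1.23 ± 0.50 (adjusted p = 0.92), CHAC1 at -0.15 ± 0.59 and IL8 at -1.57 ± 0.46 (adjusted p = 0.769). The NF-kB list had 3 of 22 genes lower adjusted over the list alone (adjusted p = 0.072 with an estimated correlation).

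The controls were compared with each other to show the background of both treatments. Between DMSO and untreated cells, 2 libraries each, edgeR and DESeq2 called 0 of 20123 genes, and 365 had an unadjusted p under 0.05 in edgeR. CHAC1 stood at -0.70 ± 0.46 and DDIT3 at -0.79 ± 0.37, and the integrated stress response list had 0 of 53 past the threshold (0 adjusted over the list alone, adjusted p = 0.561 with an estimated correlation).

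Cells without drug or radiation differed between 72 h and 24 h in edgeR's additive model of all libraries. The 24 h controls lie in inferred run A and the 72 h controls in run B, 2 libraries each, so among the controls time and run cannot be told apart. The integrated stress response was higher at 72 h than at 24 h. Of 53 genes 43 rose and 2 fell (46 and 2 adjusted over the list alone, median 1.16, adjusted p = 0.0057 with an estimated correlation). NUPR1 (3.57 ± 0.33), CHAC1 (3.40 ± 0.42), DDIT3 (3.27 ± 0.36) and GDF15 (3.19 ± 0.48) were among them, and ADM2 (3.52 ± 0.42) and HSPA5 (1.99 ± 0.32), which are not in this list, rose too. All 38 DNA replication and G1/S genes fell (38 adjusted over the list alone, adjusted p = 0.02 with an estimated correlation), as did 47 of 49 genes of G2 and mitosis (47 adjusted over the list alone, adjusted p = 0.225 with an estimated correlation) and 26 of 33 double-strand break repair genes (27 adjusted over the list alone, adjusted p = 0.0341 with an estimated correlation). RRM2 (-3.31 ± 0.34), NCAPG (-3.26 ± 0.38), CLSPN (-3.18 ± 0.30), SERPINB2 (-3.87 ± 0.44) and SNORA53 (-3.85 ± 0.50) had the largest drops, and S100P (3.52 ± 0.42) rose. In all 6145 genes differed, 3318 higher and 2827 lower, and 488 passed with the run as a covariate. The additive value draws on every library, and a model with the combination term, added after the data were examined, called 3171. In it NUPR1 (3.74), CHAC1 (3.14) and RRM2 (-2.92) passed as well, while TXNIP stood at -2.43 against -0.07 in the additive model.

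The dopamine receptor DRD2, at which ONC201 is described as an antagonist, and the receptor DRD5 had 0 reads in all 34 libraries, which allows up to 0.0536 CPM in the deepest one. The TRAIL gene TNFSF10 had 76 reads over 26 libraries, at most 10 in any, and was not tested.

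Markers of other cell types were scarce in this line. With ONC201 at 24 h 3 of 8 measured prostate luminal markers fell (3 adjusted over the list alone, adjusted p = 0.279 with an estimated correlation). Of 4 neuroendocrine markers 1 rose and 1 fell (1 and 1 adjusted over the list alone, adjusted p = 0.574 with an estimated correlation). Immune cell markers had 0 of 4 past the threshold in edgeR (0 adjusted over the list alone, adjusted p = 0.994 with an estimated correlation). Of 6 fibroblast markers 1 rose and 2 fell (1 and 2 adjusted over the list alone), and of 3 endothelial markers 1 fell (1 adjusted over the list alone), both with adjusted p = 0.546 with an estimated correlation. At 72 h 3 of 6 fibroblast markers fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -1.45 (adjusted p = 0.124 with an estimated correlation, and 1.24e-07 by fry for a shift on balance one way). Of 8 luminal markers 4 fell and 2 rose (5 and 3 adjusted over the list alone, median -1.05, adjusted p = 0.273 with an estimated correlation). Of 4 immune cell markers 1 fell (1 adjusted over the list alone, adjusted p = 0.452 with an estimated correlation), of 3 endothelial ones 1 fell (1 adjusted over the list alone, adjusted p = 0.298 with an estimated correlation), and of 4 neuroendocrine ones 1 rose and 1 fell (1 and 1 adjusted over the list alone, adjusted p = 0.75 with an estimated correlation).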

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

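Chosen only after the result was seen were the tests of the culture or label and of a swap for the 72 h libraries near the unirradiated ones, of run and dose for radiation at 72 h, and of run and the 24 h 2 Gy library for the mitochondrial transcripts.

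A difference between the times, tested as the ONC201 effect at 72 h minus that at 24 h, drew attention to 11 genes that had been fixed in advance. On the log2 scale it was -3.486 for CHAC1, -2.191 for MKI67, -2.167 for CCNB1, -1.92 for TRIB3, -1.641 for HMGCS1 and -1.534 for ASNS. It was -1.201 for DDIT3, -1.006 for XBP1, -0.8335 for ATF4, -0.8198 for KLF9 and -0.6055 for MYC. The 8 Gy effect at 72 h minus that at 24 h was 1.868 for MKI67 (adjusted p = 0.0386) and 2.688 for HMGCS1 (adjusted p = 0.00764). The ONC201 effect on GDF15 differed by 2.614 between irradiated and unirradiated cells at 72 h. Data outside the gene counts showed a signal in the 24 h 2 Gy library, where 90.53% of aligned reads were multi-mapped (95% Wilson interval 90.5 to 90.5), against 32.6% to 41.0% in the control libraries.

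In 2 libraries of 72 h, 4 Gy with 5 µM and 8 Gy with 10 µM, genes chosen for a gap of more than 1 in log2 between both libraries of 2 and 4 Gy and both of 0 Gy without ONC201 at 72 h (116 higher and 127 lower) lay near the level of the unirradiated ONC201 libraries. On a scale with the unirradiated ONC201 libraries at 0 and the other irradiated ones at 1 they stood at 0.174 and 0.297, where 3 unirradiated libraries spanned -0.25 to 0.194 and 7 irradiated ones 0.749 to 1.22. Trends with GC content and gene length are argued against, since the higher of the 2 stood at 0.282 with them removed, and so is a swap with an unirradiated ONC201 library, whose highest position was 0.194. A culture that was not irradiated, or a wrong label, is consistent with the position of the 4 Gy with 5 µM library (0.174), while the position of 8 Gy with 10 µM (0.297) lies between the ranges and leaves this open. A biological difference between these cultures stays open as well and was not tested. Library composition stays open too and was not tested. Short noncoding RNAs took 11.4% and 9.79% of gene reads in these 2 libraries and 14.3% to 26.9% in the 7 irradiated ones. In the unirradiated ONC201 libraries they took 8.62% to 18.8%.

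A radiation response at 72 h was seen at 2 Gy already in 34 higher and 29 lower genes. They were chosen for a gap of more than 1 in log2 between 7 irradiated and 3 unirradiated ONC201 libraries of 72 h. Libraries of 2 Gy were among the 7, so genes that respond only at higher doses could not enter. Over the chosen genes the median difference without ONC201 was 1.051 at 2 Gy, 1.801 at 4 Gy and 1.391 at 8 Gy. Among those 10 ONC201 libraries, which leave out 4 Gy with 5 µM and 8 Gy with 10 µM, it was 1.963, and 0.042 over 2, 4 and 8 Gy at 24 h. The run is argued against as the whole cause, since the difference within run B was 0.776 of that 1.963 across runs, and 0.772 against each control alone. The libraries without ONC201 cannot decide on a response in proportion to dose: the 8 to 2 Gy ratio was 1.32 (1.17 and 1.19 against each control), but it rests on 1 library per dose, and that of 8 Gy carries 4 Gy in its treatment label and lies in another run. On the 0 to 1 scale given above, the ONC201 libraries of run C stood at 1.001, 1.029 and 1.223 at 2 Gy and at 0.876, 0.297 and 1.034 at 8 Gy. The genes of that scale were chosen for a gap at 2 and 4 Gy, so genes that respond only at 8 Gy could not enter. The positions therefore cannot decide on proportion to dose with ONC201. For these genes no position at 8 Gy was above the highest at 2 Gy, but 0.297 belongs to a library that lay near the unirradiated ones. Short noncoding RNA shares differed between the libraries of 2 and 8 Gy too. A response near its ceiling at 2 Gy stays open, as does any handling that irradiated cultures shared, since no sham-irradiated library is labelled. Library composition stays open as well and was not tested. Within run B, short noncoding RNAs took 18.1% and 21.3% of gene reads at 2 and 4 Gy without ONC201. They took 10.2% and 9.34% in the DMSO and untreated libraries of 72 h.

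The mitochondrially encoded transcripts that were lower with ONC201 at 24 h stayed lower in each test. The median log2 fold change was -1.50 within run A (13 of 13 genes lower), -1.29 with GC and length trends removed (12 of 13), and -0.988 without the 24 h 2 Gy library (8 of 13), so each of these 3, taken singly, is argued against as the whole cause. The value within run A still includes the 24 h 2 Gy library, so run and that library were not removed together. An effect of ONC201 on mitochondrial transcripts is a hypothesis that stays open, found and tested on the same data, and reads shared with nuclear copies were not tested.

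Other assignments of the doses to the same libraries, which did not hold the inferred run fixed, gave as many genes, the real one included, as follows. For ONC201 at 24 h it was 1 of 60 (real 3496, highest other 126) and at 72 h 1 of 60 (real 6807, highest other 6218), under 5% in both. The doses of 24 h and 72 h were shuffled together, and all libraries share 1 spread per gene. A signal at 1 time thus widens the spread of the shuffled fits at the other, so these counts argue against chance for the drug over both times together. The 6218 came from an assignment that left all 5 drug-free 72 h libraries at 0 µM. The 72 h minus 24 h difference gave 2 of 60 (real 1926, highest other 5063), under 5% too. The 5063 came from the same assignment, which had 6218 genes at 72 h and 0 at 24 h (edgeR), so it set the drug contrast of 72 h against a scrambled one of 24 h. Radiation at 24 h gave 1 of 40 (real 73, highest other 0). The 72 h radiation signal widens the spread of the shuffled fits and lowers their 24 h counts, so this cannot exclude chance at 24 h. The run cannot be excluded either, since 0 genes passed with the run as a covariate (edgeR, 958 at an unadjusted p under 0.05). Radiation at 72 h gave 2 of 40 (real 2719, highest other 3112) and the combination at 72 h 3 of 40 (real 160, highest other 1008), and chance cannot be excluded for these 2. The 1008 is several times the real count, which points to a structure of the samples that was not traced. Where the real count is 0 every assignment gives as many, so 60 of 60 for ONC201 dose at 24 h (highest other 81), 60 of 60 at 72 h (highest other 2967) and 40 of 40 for the combination at 24 h (highest other 2) say nothing about chance.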

How the results depend on the processing

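Chosen only after the data were seen were the fits within inferred run A or B and those without the 2 or 3 doubtful libraries. So were those with GC and length offsets and those with the share of reads outside genes as a covariate. The model with the combination term for time was added then too.

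Most calls of single focus genes kept their direction and their side of the threshold: for ONC201 at 24 h 661 of 688 planned comparisons (27 fell short of the threshold) and 63 of 64 added ones, at 72 h 718 of 792 and 79 of 90, and for radiation at 72 h 191 of 220 and 22 of 25. Most of these comparisons leave out 1 library, and single settings ended more. In the unirradiated libraries alone, 3 with ONC201 and 2 without, 15 of 16 called focus genes lost their call at 24 h, with ASNS the exception, among them CHAC1 (3.62, adjusted p = 0.153), DDIT3 (2.18, adjusted p = 0.234), ATF4 (1.32, adjusted p = 0.145) and MT-CO1 (-1.67, adjusted p = 0.133). Their folds stayed near those of all libraries (3.53, 2.13, 1.45 and -1.62), and fewer libraries entered. GDF15 reversed for ONC201 at 72 h, to -0.198 (adjusted p = 0.831) within run B and -0.121 (adjusted p = 0.87) in the unirradiated libraries alone. For ONC201 at 24 h MKI67 (-0.77, adjusted p = 0.0375) ended at an adjusted p of 0.231 without the 24 h 2 Gy library. It also fell short with the run as a covariate (-0.80, adjusted p = 0.118) and without the untreated libraries (-0.79, adjusted p = 0.0531). For ONC201 at 72 h ATF3 (0.70, adjusted p = 0.0291) ended at 0.189 without the 72 h 2 Gy library. ATF3 also fell short at 72 h with the run as a covariate (0.46, adjusted p = 0.362). ATF4 (0.55, adjusted p = 0.0889) and DDIT3 (0.87, adjusted p = 0.0683) fell short in that fit too. For radiation at 72 h CCNB1 (1.24, adjusted p = 0.0165) ended at 0.171, MKI67 (1.13, adjusted p = 0.03) at 0.38 and TNFRSF10B (-0.46, adjusted p = 0.029) at 0.128 without the library of 8 Gy with 15 µM, and CCND1 (-0.63, adjusted p = 0.013) at 0.105 without the 72 h 8 Gy library. These 4 also ended with the run as a covariate, which coincides with 8 Gy at 72 h: CCNB1 (1.48, adjusted p = 0.297), MKI67 (1.26, adjusted p = 0.39), TNFRSF10B (-0.37, adjusted p = 0.593) and CCND1 (-1.01, adjusted p = 0.105). In the 72 h libraries alone they stood at adjusted p values of 0.116, 0.143, 0.143 and 0.0991. The cause was not tested.

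Counts of called genes stayed within 1.5 times in 10 of 14 alternatives for ONC201 at 24 h, 13 of 16 at 72 h, 10 of 11 for their difference, 2 of 15 for radiation at 24 h, 8 of 17 at 72 h, 9 of 13 for the combination at 24 h, 4 of 14 at 72 h and 9 of 11 for time. The others are given here by setting, and the cause was not tested except where fewer libraries or genes entered.

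DESeq2 gave 546 genes for radiation at 24 h, 7 for the combination at 24 h and 447 at 72 h. Without a filter on low counts there were 1 and 45 genes for ONC201 dose at 24 h and 72 h, 550 for radiation at 24 h, 28 and 427 for the combination at 24 h and 72 h, and 4 for DMSO. At least 50 counts in 8 libraries gave 117 for radiation at 24 h. With the inferred run as a covariate there were 1988 genes for ONC201 at 24 h, 3975 at 72 h and 695 for their difference, 0 for radiation at 24 h (edgeR, 958 at an unadjusted p under 0.05) and 104 at 72 h, 1 for the combination at 72 h and 488 for time. Only the libraries of that time gave 5461 for ONC201 at 24 h, 1842 and 675 for radiation at 24 h and 72 h, and 24 and 1 for the combination.

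Without the DMSO libraries the combination at 72 h had 509 genes, and without the untreated ones 22, with 191 for radiation at 24 h. With the 72 h 8 Gy library taken as 4 Gy radiation at 72 h had 1295. Without the 3 doubtful libraries radiation had 509 genes at 24 h and 4267 at 72 h and the combination at 72 h 392, and without the 2 of 72 h these were 467, 4237 and 381. GC and length offsets gave 208 for radiation at 24 h and 377 for the combination at 72 h. Run A alone gave 656 for radiation at 24 h, which rests on its 1 library at 8 Gy, assumed to vary as the others do, and 85 for the combination, which there comes from 2 and 4 Gy. Run B alone gave 1371 for ONC201 at 72 h, with an error that rests on its DMSO and untreated libraries alone, and 392 for radiation at 72 h. Unirradiated libraries alone gave 5 genes for ONC201 at 24 h and 1431 at 72 h. The 85 within run A draw in part on the 24 h 2 Gy library, since the irradiated libraries without ONC201 behind them are those of 2 and 4 Gy.

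A linear trend per µM gave 1198 for ONC201 at 24 h, and one per Gy 0 for radiation at 24 h (edgeR, 2241 at an unadjusted p under 0.05) and 240 at 72 h. The mean of 2, 4 and 8 Gy gave 316 at 24 h and 6216 at 72 h. Gy times µM as a linear term gave 0 for the combination at 72 h (edgeR, 1579 unadjusted). Libraries without ONC201, with a trend per Gy, gave 0 at 24 h (edgeR, 699 unadjusted) and 0 at 72 h (2886 unadjusted). The model with the combination term gave 3171 for time.

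Of 29 lists, camera with its preset correlation called 18 for ONC201 at 24 h, 16 at 72 h, 14 for their difference, 9 and 11 for dose, 8 and 11 for radiation, 10 and 7 for the combination, 16 for DMSO and 11 for time. With an estimated correlation these were 3, 2, 3, 0 and 0, 0 and 2, 0 and 0, 0 and 3. By fry one way there were 9 for the difference, 0 and 0 for dose, 0 for radiation at 24 h, 1 and 0 for the combination and 0 for DMSO. By fry in either direction there were 25 for ONC201 at 72 h, 0 and 0 for dose, 3 for radiation at 24 h, 1 for the combination at 24 h, 0 for DMSO and 24 for time. The run as a covariate gave 14 lists for radiation at 24 h.

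With each of the 34 libraries left out in turn the counts ranged from 2421 to 3889 for ONC201 at 24 h, 5586 to 7207 at 72 h, 1439 to 2325 for their difference, 2 to 373 for radiation at 24 h, 960 to 4018 at 72 h, 28 to 575 for the combination at 72 h and 5418 to 6658 for time. They were 0 to 0 for dose at each time, the combination at 24 h and DMSO. Where this left a condition without a library, the rest were assumed to vary alike.

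No paired analysis was possible because every replicate is numbered 1 and each condition has 1 library. ONC201 at 72 h within run C was not estimated, since run C holds no 0 Gy library and the model as set could not be fitted there. Run C also holds only 1 library without the drug. Depth limits what can be said of genes with few reads, such as FGF21, and of the 24 h 2 Gy library.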

Other observations

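Chosen only after the result was seen were the tests of the run for TXNIP and of ARRDC4 in the model with the combination term.

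Single genes that the comparisons did not name moved with ONC201. The splicing regulator ESRP1, which maintains epithelial isoforms, rose by a log2 fold change of 2.26 ± 0.16 at 24 h (SE, adjusted p = 2.99e-11, n = 12 against 5) and passed at 72 h too (adjusted p = 9.21e-13). The epithelial-mesenchymal transition list that holds it went both ways, with 5 of 23 higher and 4 lower at 24 h (6 and 4 adjusted over the list alone, adjusted p = 0.596 with an estimated correlation), and 4 higher and 6 lower at 72 h (4 and 6 adjusted over the list alone, adjusted p = 0.907 with an estimated correlation). The cytokine IL6 rose by 2.00 ± 0.41 at 72 h (adjusted p = 0.000268), while IL8 fell by 2.04 ± 0.25 (adjusted p = 1.32e-07). BCL2, which restrains apoptosis, rose by 1.40 ± 0.23 at 72 h (adjusted p = 1.82e-05), and its difference from the effect at 24 h was 1.55 ± 0.31 (adjusted p = 0.00119).

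TXNIP stood at 35.5 ± 7.26 CPM (SD, n = 2) in the 24 h controls and 6.57 ± 2.66 CPM (n = 2) in the 72 h controls, which gave rise to the hypothesis that these cultures had used up their glucose by 72 h. ARRDC4, chosen outside the rule for naming genes because the same glucose-sensing factor controls it, should then be lower at 72 h. In the additive model, the test written first, ARRDC4 differed by -0.711 (adjusted p = 0.104) and TXNIP by -0.07 (adjusted p = 0.945), which left it undecided. In the model with the combination term, tried because the first was undecided, ARRDC4 differed by -1.40 (adjusted p = 0.00327) and TXNIP by -2.43 ± 0.286 (adjusted p = 3.07e-06), which is consistent with the hypothesis but was picked after the first had failed to decide. TXNIP was higher by 3.83 (adjusted p = 0.0195) in 2 and 4 Gy than in 0 Gy libraries within run B, while ARRDC4 did not pass there (1.68 ± 0.359, adjusted p = 0.053). Low TXNIP is therefore not shared by all libraries of that run, but this compares radiation doses and cannot separate run from time in the controls. For ARRDC4 radiation at 72 h gave 1.30 ± 0.269 (adjusted p = 0.00236) and the combination -1.65 ± 0.357 (adjusted p = 0.0217), both across runs. Glucose was not measured in the sources used here, and time and run cannot be told apart in the controls.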
